A study of Danio rerio with 8 samples.

How the data were processed

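Single-cell RNA was measured in whole kidney marrow of zebrafish aged 8 months. Per the labels, Zebrabow embryos received Cas9 mRNA with guide RNAs against 20 genes, and control siblings received 2 control guides. Zebrabow fish carry recombining fluorescent protein genes, so that cells descended from 1 recombined cell share a colour. The labels name 2 control and 3 mutant libraries of unsorted marrow, and 3 dominant libraries of cells sorted from the same 3 mutant fish for the colour that prevailed. The marrow was dissociated mechanically after bleeding of the heart, and libraries were made with the 10x Genomics v2 kit, per the labels' protocols. Cell Ranger 3.1.0, Seurat 3.0 and the genome build GRCz11 are named per the submitters' processing notes, which give neither the role of each tool nor an annotation or a cell filter.

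The deposited values are raw UMI counts per gene and cell in 1 table of 17357 genes and 39424 cells. No normalisation was applied to these deposited counts. The lowest total of a deposited cell was 499 UMIs, and each deposited gene was seen in at least 3 cells. No annotation of cell types accompanies the counts. Each cell belongs to 1 of 8 numbered libraries, and the numbers match no title, description or other label. The table alone therefore does not link a library to the control, mutant or dominant group, or to a fish. The order of the libraries and the expression values in them were not used to fill this gap. Libraries are called library 1 to library 8 after the deposited numbers.

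All comparisons planned between control, mutant and dominant libraries were therefore left out, and with them their tests, p-values and splits of the libraries. Each of the 8 libraries is reported by its own value or by the median and range over the 8 libraries, with no mean, standard deviation or test that would treat them as replicates. Cell classes are compared inside each library. A gene or list is called higher or lower only by the number of libraries in which its value was so, and this count is descriptive. Libraries 1 to 8 also include pairs made from 1 fish, so that a count of 8 libraries is not a count of 8 fish.

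Cells with at least 500 UMIs, at least 200 genes and at most 10% of UMIs from mitochondrial genes were kept, which left 38321 cells. Doublets were called in each library with Scrublet as included in scanpy 1.11.5, at an expected rate of 6%. The caller marked 208 cells, or 0.543%, of which 194 were in library 8 and at most 4 in any other library, so the caller did not work in libraries 1 to 7. These 208 cells were left out, and 38113 cells were kept. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with the library as batch key, and 30 principal components and 20 neighbours gave 30 Leiden clusters at a resolution of 1. Batches were not integrated. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9 were used.

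Marker lists of 12 cell types were fixed before the data were examined. A marker counted for a cluster at a log2 ratio of at least 1.5 to the other cells, with 10 CPM added to both. A cluster took the name of the type with the most such markers if it had at least 3. Clusters led by genes of another type stayed unnamed. So did clusters with a median UMI count under 1/3 of that of their libraries and no marker among their top 10 genes. With these rules 23 clusters were named and 7 stayed unnamed. The names were rebuilt from markers and are written as progenitor-like, neutrophil-like and so on.

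Counts were summed per library over the cells of each class and divided by the total of the class in the library, to give CPM. TMM factors over 7 classes in 8 libraries scaled these totals, and the result is called normalised CPM. The median TMM factor was 0.409 in erythroid-like sums and 1.77 in thrombocyte-like sums, so values in these 2 classes depend on this scaling most. Values of single clusters and of reporter genes are plain CPM. Exact Poisson intervals (95%) are given for CPM and exact Clopper-Pearson intervals (95%) for shares of cells. Where a count was 0, the level that 3 counts would give is stated as the limit. These intervals and limits cover counting error only.

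Gene lists were fixed before the data were examined. Those reported hold inflammatory effectors, negative regulators of inflammation, immediate early genes, heat shock, interferon response, antigen presentation, neutrophil granule and oxidase, macrophage and complement, haem synthesis and erythroid, globin, cell cycle, stem and progenitor regulators, unfolded protein and amino acid stress, human clonal haematopoiesis genes, cytosolic ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, and markers of kidney, endothelial and stromal, B, T and NK, and thrombocyte cells. In a comparison of 2 classes, a member counted as measured with at least 50 counts over both, and markers that had named either class were left out. Summed lists and their ratios hold every member, also such markers and members with few counts. Where a list shares markers with a class, its ratio thus partly follows from the naming. Some genes are in more than 1 list.

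The genes asxl1, nr4a1, socs3a, nfkbiaa, il1b and atf3 were chosen before the data were examined, as genes known from the study. The planned choice of further genes rested on adjusted p-values and could not be applied. It was replaced, after the data were seen, by up to 4 members per list with the most counts among those higher, or lower, in all 8 libraries, and the text names some of these. Genes named for differences between libraries were also chosen after their values were seen. For the ratio of the highest to the lowest library, counts under 3 were set to 3.

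The count of libraries was tested on counts simulated for neutrophil-like over progenitor-like cells. Among 2728 genes, all of 200 genes simulated with a fold of 2 were higher in all 8 libraries (100%), while 0.87% of the unaltered genes were higher or lower in all 8. Counting error was the only variation simulated, so this says nothing on differences between libraries or fish. The 2728 genes are only part of the 17357 deposited. Both rates need not apply to members with few counts in a class, such as il1b, with 2 neutrophil-like counts against 0 progenitor-like counts in library 2.

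Alternatives fixed before the data were examined and run were a minimum of 1000 UMIs and 500 genes, doublets kept, cells assigned singly by marker score, and shares without erythroid-like cells. Alternatives added after seeing the data were clusters made without the listed genes, removal of cells with a doublet score of at least 0.25, a low-UMI neutrophil cluster counted with its class, CPM without globin transcripts, CPM without TMM, and each library left out in turn. The sorted colour, the targeted sites and the fish of origin were not analysed here.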

Results

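The data are UMI counts from kidney marrow, the site of blood formation in adult zebrafish, in 8 single-cell libraries. By the labels, 2 libraries are control, 3 are mutant and 3 are dominant, the last being cells of the prevailing Zebrabow colour sorted from the 3 mutant fish. The counts do not say which library is which, so no value below is assigned to control, mutant or dominant marrow, and no group is compared with another. Library 1 held 5959 cells and 37542456 UMIs, library 2 held 3687 cells and 20308160, library 3 held 2883 cells and 19450284, and library 4 held 4935 cells and 34054976. Library 5 held 3260 cells and 30134916 UMIs, library 6 held 4775 cells and 33142640, library 7 held 5435 cells and 27897500, and library 8 held 8490 cells and 62254848. Median depth lay between 2599 UMIs per cell in library 7 and 7926.5 in library 5.

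The study's title concerns resistance to inflammation in clonal haematopoiesis, the outgrowth of blood cells from 1 mutated stem cell, and its design concerns the effect of mutagenesis on marrow cells. Without the groups, the counts could address 3 narrower questions. Which cell classes did each library hold, which classes carried the inflammatory programmes and their negative regulators, and how far did the libraries differ in the genes known from the study?

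Transcripts of asxl1, a chromatin regulator often mutated in clonal haematopoiesis and known from the study as a targeted gene, were scarce in every class examined. In progenitor-like cells the median was 5.93 normalised CPM, from 0 counts in the 125 cells of library 2, which allows up to 2.56, to 7.72 (95% interval 5.46 to 10.6) in library 8. In neutrophil-like cells the median was 4.25 (2.18 to 5.61 over 8 libraries) and in macrophage-like cells 3.33 (1.80 to 5.49). The highest and lowest macrophage-like values, from 29 and 5 counts, had intervals of 3.68 to 7.89 and 0.584 to 4.20. Small insertions and deletions need not alter transcript number, and tags from the 3′ end need not cover the edited site, whose position was not analysed. These values therefore do not check the labels.

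Neutrophil-like cells were the most numerous named class in libraries 2, 6, 7 and 8, and erythroid-like cells in libraries 1, 3, 4 and 5. Neutrophil-like cells made up 24.1, 30.0, 13.9, 13.8, 16.1, 39.1, 35.7 and 32.5% of kept cells in libraries 1 to 8. Erythroid-like cells made up 35.6, 27.8, 35.2, 28.5, 38.2, 8.22, 0.760 and 12.5%. The lowest erythroid-like share, 39 of 5130 cells in library 7, had an exact 95% interval of 0.541 to 1.04%, and the highest, in library 5, one of 36.5 to 39.9%. Macrophage-like cells had a median share of 10.4% (5.69 to 16.5 over 8 libraries), B-like cells 11.95% (9.56 to 18.4), T/NK-like cells 3.29% (1.93 to 4.52) and thrombocyte-like cells, the fish counterpart of platelets and their precursors, 1.21% (0.885 to 1.72). Progenitor-like cells, marked by gata2b and csf1rb among their leading genes, made up 2.87, 3.46, 6.26, 6.07, 4.45, 14.4, 6.65 and 8.74% of libraries 1 to 8. Unnamed clusters held 9.11 to 29.2%, and the largest of them carried few UMIs (median 651) and neutrophil markers.

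These shares depended on the filter and the clusters. With at least 1000 UMIs and 500 genes per cell, the median share was 1.55% for progenitor-like, 18.7% for macrophage-like, 18.7% for erythroid-like, 4.78% for B-like and 1.58% for T/NK-like cells. It was 11.2% for erythroid-like cells in clusters made without the listed genes, where a cluster of 5006 cells with erythroid markers stayed unnamed because liver genes led it, 2.64% for thrombocyte-like cells assigned singly by marker score, and 18.0% for B-like cells once erythroid-like cells were left out of the total.

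**Figure D1:**
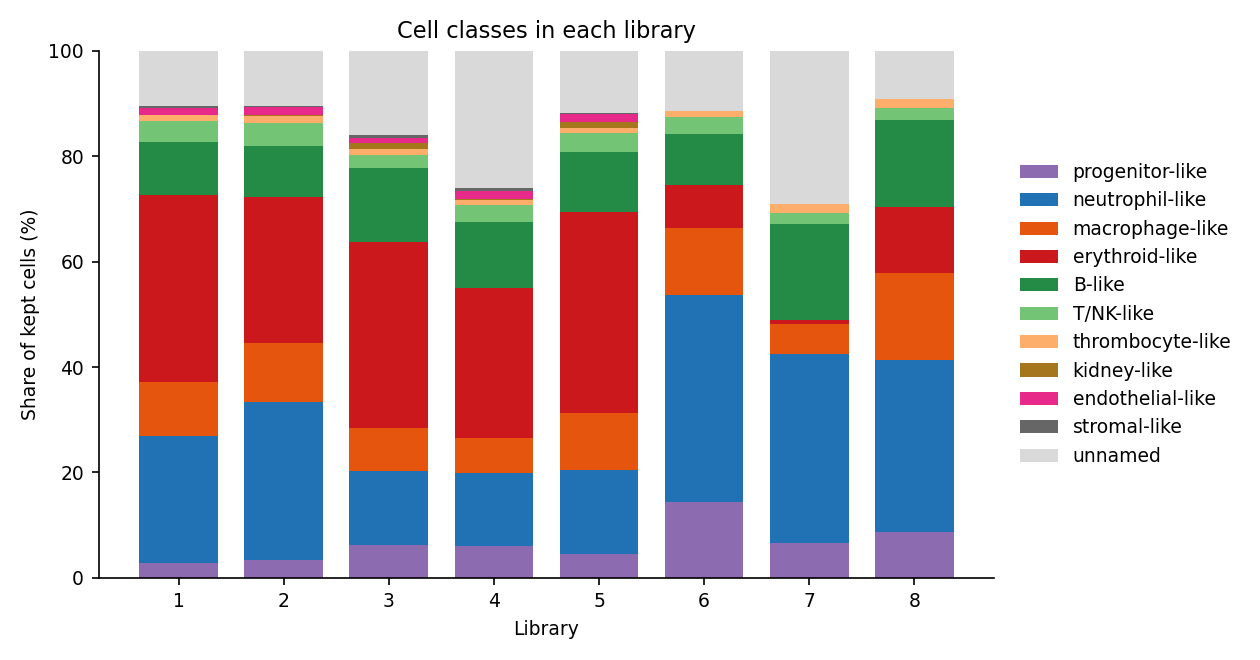
Stacked bars give the share of kept cells (%, vertical axis) in each class for libraries 1 to 8 (horizontal axis), with unnamed clusters in grey. The erythroid-like share ran from 0.760% in library 7 to 38.2% in library 5, and the progenitor-like share from 2.87% in library 1 to 14.4% in library 6.

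Inflammatory effectors lay far higher in neutrophil-like than in progenitor-like cells of every library. The summed list was 14.4 times higher at the median (12.5 to 17.5 over 8 libraries). Of 11 measured members, 5 were higher in all 8 libraries, 1 was lower in all 8 and 5 were mixed. Without TMM 6 were higher and 0 lower. The cytokine gene il1b is counted among the 5, although in library 2 it had 2 counts against 0. The median of timp2b, an inhibitor of matrix proteases, was 354 normalised CPM (302 to 561) against 6.07 (1.11 to 19.4) in progenitor-like cells. The cytokine il34 stood at 178 (133 to 259) against 15.7 (7.69 to 27.1), and the cytokine gene tnfb at 58.6 (2.68 to 136) against 2.69 (0 to 6.65). The summed list had a median of 1057 in neutrophil-like cells, so timp2b and il34 made up much of it. The death ligand tnfsf10 was the member lower in all 8 libraries.

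Negative regulators of inflammation were also higher in neutrophil-like cells, 4.14 times for the summed list (2.95 to 5.79). Of 25 measured members, 13 were higher in all 8 libraries, 2 were lower in all 8 and 10 were mixed. The transcription factor gene cebpb, counted here because the fixed list holds it, had a median of 2463 normalised CPM (1097 to 4858) against 527 (54.7 to 888). Whether it restrains inflammation in these cells was not examined. The summed list had medians of 4969 and 1480.4, so its ratio leans heavily on this 1 gene. The NF-kB inhibitor nfkbiab stood at 306 (154 to 411) against 119 (73.4 to 164), and the phosphatase gene dusp1, which switches off stress kinases, at 204 (52.7 to 580) against 44.5 (13.3 to 131). The 2 lower members were klf2a, a quiescence factor, and cish, an inhibitor of cytokine receptors. The genes atf3, socs3a and socs3b were among the leading genes of 1 of the 5 neutrophil-like clusters, which held 71.9% of these cells in library 6 and 51.4% in library 7. The clusters differed widely: the regulators summed to 15341 and 11737 plain CPM in 2 of them, 4022 and 3146 in 2 others and 1708 in the last, near the progenitor-like median of 1480.4, and the effectors to 4688, 1341, 803, 948 and 305 in the same order. In clusters made without the listed genes, the counts for both lists stayed within 1.5 times of these.

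Other lists also held members that differed between neutrophil-like and progenitor-like cells, with no share over all genes to set beside them. Of 12 measured members of the neutrophil granule and oxidase list, 10 were higher in all 8 libraries, among them srgn, a granule proteoglycan, at 10225 normalised CPM (8212 to 11997) against 214 (93.1 to 429). In the macrophage and complement list 9 of 16 were higher, among them cfd, complement factor D, at 2233 (1315 to 3460) against 71.8 (20.5 to 103.9), and 1 was lower. The unfolded protein and amino acid stress list had 12 of 27 members higher and 3 lower, with xbp1, a transcription factor of that response, at 1139.97 (616 to 1838) against 385 (155 to 495). Among stem and progenitor regulators 3 of 10 were higher and 4 lower, and spi1b, a myeloid transcription factor, stood at 704 (546 to 787) against 57.1 (46.1 to 90.2). Mitochondrially encoded genes had 6 of 13 higher and none lower. Oxidative phosphorylation had 20 of 85 higher and 9 lower, or 14 lower without library 5.

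Cytosolic ribosomal proteins were lower in neutrophil-like cells, with 75 of 79 members below progenitor-like cells in all 8 libraries and a summed ratio of 0.388 (0.299 to 0.516). Of 35 cell cycle genes 10 were lower and 0 higher, although the summed list was higher in 4 of 8 libraries, with a ratio of 0.975 (0.539 to 1.2002) and 4413 plain CPM in 1 of the 5 clusters. Among the lower genes hmgb2b, a chromatin protein abundant in dividing cells, stood at 161 (83.0 to 223) against 549 (236 to 921). Antigen presentation had 8 of 22 members lower and 1 higher, with cd74a, the chain that guides MHC class II, at 27.2 (22.4 to 41.2) against 685 (508 to 869). In the heat shock list 6 of 13 were lower and 0 higher, and hspa8, a constitutive chaperone, stood at 1732 (1307 to 2094) against 2749.7 (2163 to 3361).

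Several lists went both ways. Of 27 immediate early genes 4 were higher and 6 lower, or 10 lower without library 1, and egr1, a growth-factor response gene, was at 13.9 (2.24 to 32.9) against 135 (24.8 to 231). The interferon response had 3 of 18 higher and 4 lower. Human clonal haematopoiesis genes had 8 of 43 higher and 9 lower, which became 9 and 6 without TMM, and idh1, a cytosolic isocitrate dehydrogenase, stood at 208 (168 to 273) against 14.5 (8.48 to 22.9). Markers of other cells were few here. Members higher in all 8 libraries numbered 1 of 4 for kidney, 1 of 2 for endothelial and stromal, 1 of 5 for B, or 2 without library 7, 2 of 8 for T and NK, and 1 of 5 for thrombocyte, and members lower numbered 0, 0, 1, 1 and 2.

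Abundant transcripts of 1 class were also seen in others, and no test here separates free RNA from doublets as their source. The lysozyme gene lyz, at a median of 96911 normalised CPM in neutrophil-like cells, was found at 849 (350.1 to 1834) in progenitor-like and 3729 (761 to 8700.2) in B-like cells. Beta-globin hbba1 was at 306 (16.7 to 655) in progenitor-like and 541 (31.0 to 1136) in neutrophil-like cells, each lowest in library 7. Of 4 measured globin genes, 2 were higher in neutrophil-like cells in all 8 libraries, or 4 without library 3. Of 16 members of the haem synthesis and erythroid list 3 were higher and 2 lower, or 1 lower without TMM.

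**Figure D2:**
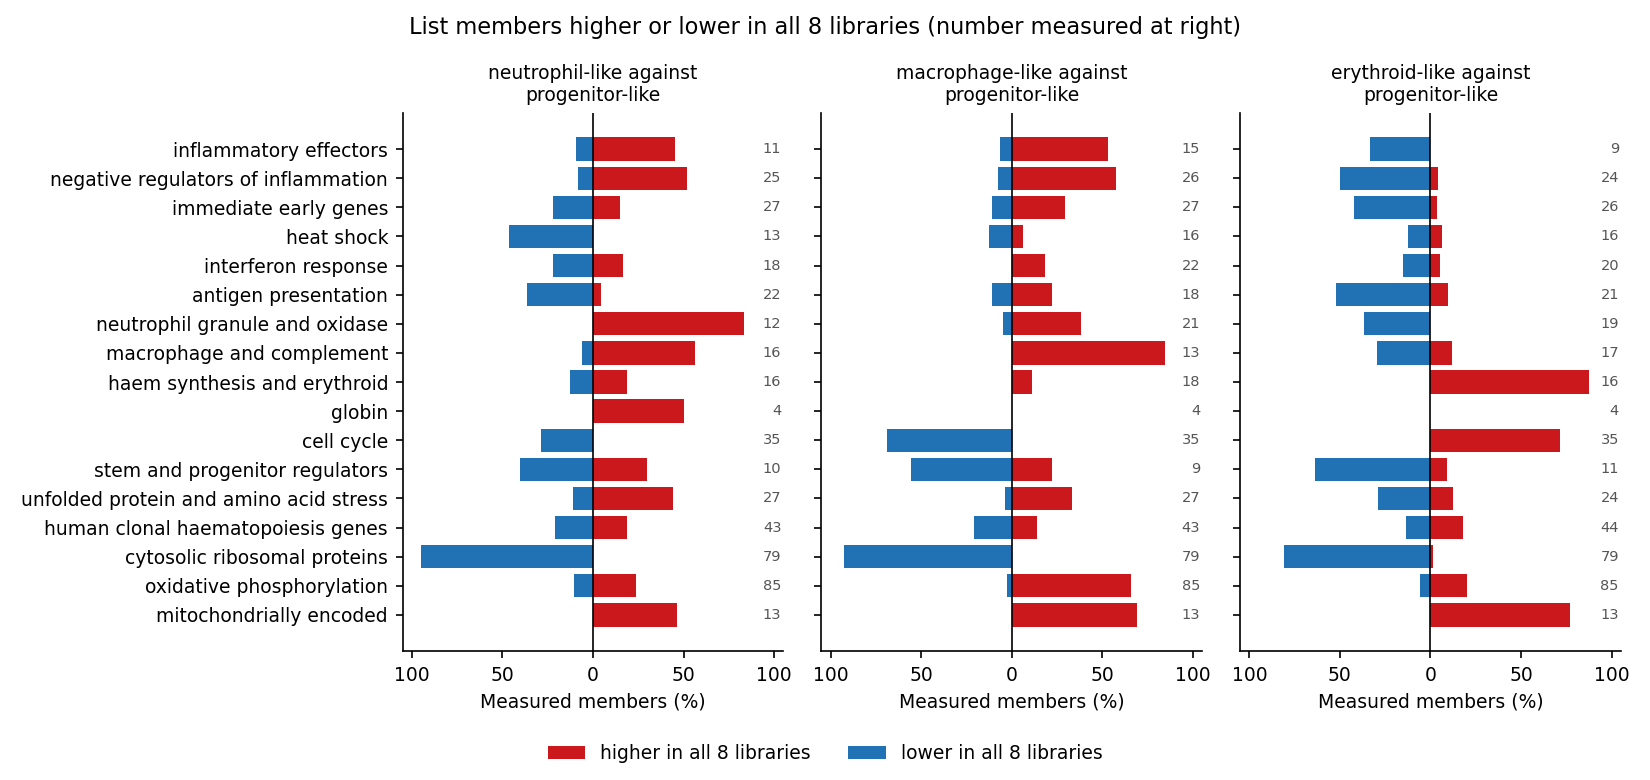
Bars give the share of measured list members (%, horizontal axis, 0 at the centre) that were higher (red, to the right) or lower (blue, to the left) in all 8 libraries, in neutrophil-like, macrophage-like and erythroid-like cells against progenitor-like cells. The number measured stands at the right, and among 79 ribosomal protein genes 75, 73 and 64 were lower in the 3 comparisons.

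Macrophage-like cells also exceeded progenitor-like cells in inflammatory effectors, 7.01 times for the summed list (4.89 to 12.7). Of 15 measured members 8 were higher in all 8 libraries, il1b with 6 counts against 0 in library 2 among them, 1 was lower and 6 were mixed. The chemokine gene ccl34a.4 had a median of 322 normalised CPM (50.9 to 947) against 0.249 (0 to 4.88), and the inflammatory caspase gene caspa stood at 47.2 (30.1 to 77.3) against 20.4 (10.3 to 29.04). Negative regulators were 3.77 times higher (2.39 to 7.60), with 15 of 26 members higher in all 8 libraries, 2 lower, or 4 without library 2 and 1 without TMM, and 9 mixed. Here too cebpb made up much of the summed list, with a median of 2461 against 4653 for the list. The annexin gene anxa1a, which restrains neutrophil influx, stood at 615 (228 to 1126) against 14.3 (7.55 to 30.9), and tsc22d3, a glucocorticoid-induced regulator, at 245 (143 to 697) against 71.0 (35.1 to 217). Macrophage-like cells of libraries 4 and 7 fell mostly in 1 cluster that held 71.8 and 78.4% of them, and those of the other libraries in another that held 80.7 to 91.4%.

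Of 85 oxidative phosphorylation genes 56 were higher in macrophage-like cells in all 8 libraries and 2 lower, with cox4i1, a subunit of cytochrome oxidase, at 784 (613 to 907) against 383 (307 to 497). The macrophage and complement list had 11 of 13 higher, led by lgals2a, a galectin, at 3137 (2066 to 4788) against 106 (85.2 to 139). The 2 main macrophage-like clusters, each named by 7 of 14 markers, nearly lacked the macrophage genes mpeg1.1 (4.003 and 1.55 CPM), marco (5.09 and 0.111) and csf1ra (1.14 and 0), whereas a small cluster held them at 473, 2705 and 15.9. Antigen presentation had 4 of 18 higher and 2 lower, and the MHC class II chain gene cd74b stood at 1366 (506 to 1942) against 501 (342 to 668). Its plain CPM was 199.7 in the main cluster of libraries 4 and 7, 1113 in that of the other libraries, and 6375 and 4109 in 2 small clusters. Of 27 immediate early genes 8 were higher and 3 lower, with junba, an AP-1 subunit, at 746 (594 to 1716) against 213 (1.71 to 428). Cell cycle genes were lower in 24 of 35 cases and higher in 0, although only 10 were lower without TMM, and stmn1a, a microtubule regulator, stood at 44.7 (14.4 to 71.1) against 276 (159 to 647). The list summed to 4652 plain CPM in the main cluster of libraries 4 and 7 and 1165 in that of the other libraries. The progenitor-like median was 3206 normalised CPM. Ribosomal proteins were lower in 73 of 79 cases. The de novo DNA methyltransferase gene dnmt3ab, of the clonal haematopoiesis list, stood at 7.15 (3.17 to 17.6) against 42.0 (13.1 to 64.7), and of the 43 measured members 6 were higher and 9 lower, or 8 and 2 without TMM.

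Neutrophil-like and macrophage-like cells divided the inflammatory effectors between them. Of 13 measured members 6 were higher in macrophage-like than in neutrophil-like cells in all 8 libraries and 3 lower, and the summed list was lower in all 8, with a ratio of 0.494 (0.298 to 0.851). The chemokine ccl34a.4 had medians of 322 in macrophage-like and 0.321 in neutrophil-like cells, whereas il34 had 4.64 and 178 and timp2b 49.8 and 354. Much of the lower summed list thus came from il34 and timp2b. The macrophage-like clusters also differed. The effectors summed to 774 plain CPM in the main cluster of libraries 4 and 7 and 466 in that of the other libraries. In 2 small clusters they summed to 2317 and 387, against a neutrophil-like median of 1057 normalised CPM. Of 26 negative regulators 5 were higher and 7 lower, with anxa1a at 615 against 119.6 in neutrophil-like cells and atf3 at 101 against 237. Antigen presentation was higher in macrophage-like cells, 2.77 times for the summed list (1.52 to 3.51), with 7 of 19 members higher and 1 lower. Small macrophage-like clusters were highest, with 31665 and 17179 plain CPM. The main cluster of libraries 4 and 7 stood at 2789 and that of the other libraries at 5289, against a neutrophil-like median of 2484. The heat shock list was 1.99 times higher (1.69 to 2.38), with 6 of 17 members higher and 0 lower, or 1 without library 3. Ribosomal proteins had 2 of 79 members higher in all 8 libraries, but 34 without library 4 and 51 without TMM.

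Erythroid-like cells carried haem synthesis and erythroid genes at 125 times (80.1 to 197) the summed level of progenitor-like cells, and 14 of 16 measured members were higher in all 8 libraries. The sum holds all 26 genes of the list, also any that named a class, which the 16 leave out. The ratio can therefore partly follow from the naming. Without TMM the ratio was 62.5 (42.4 to 71.3), and the values of single genes in erythroid-like cells carry the same scaling. The haem pathway genes cpox and hmbsa stood at 612 (488 to 939) against 7.59 (1.09 to 11.103) and at 517 (366 to 859) against 19.5 (9.39 to 27.6). Cell cycle genes were higher in 25 of 35 cases and lower in 0, or higher in 12 without TMM, and cdk1, the kinase that drives mitosis, stood at 326 (193 to 464) against 39.5 (15.0 to 73.9). Negative regulators of inflammation were lower in 12 of 24 cases and higher in 1, or in 0 without TMM and 2 without library 6, and inflammatory effectors lower in 3 of 9. Most erythroid-like cells lay in 1 cluster in libraries 1 to 5 (55.0 to 73.0%) and in another in libraries 6 to 8 (74.4 to 82.1%), with medians of 332 and 814 genes per cell. Library 7 gave only 39 erythroid-like cells, and without it 49 rather than 17 of 85 oxidative phosphorylation genes were higher, a list with 3 higher and 24 lower without TMM. Thrombocyte-like cells, from 29 to 139 per library, had 77 of 79 ribosomal protein genes lower than progenitor-like cells in all 8 libraries. They had 9 of 35 cell cycle genes higher, or 17 without library 6 and 16 without TMM.

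B-like cells exceeded T/NK-like cells in antigen presentation, 1.56 times for the summed list (1.29 to 2.59), with 8 of 19 members higher in all 8 libraries and 0 lower. The gene cd74a stood at 2989.6 (2390.2 to 3739) against 1270.4 (900.5 to 1757). Among neutrophil granule and oxidase genes 9 of 18 were higher and 2 lower, or 5 and 3 without TMM. They included ncf1 and cybb, subunits of the NADPH oxidase, at 462 (320 to 582) against 47.3 (3.26 to 91.2) and at 116 (104.9 to 179) against 8.70 (0 to 20.3). Another 4 of the 9, lect2l, mmp13a.1, mmp9 and scpp8, are neutrophil transcripts, and lyz was also higher in B-like cells in 7 of 8 libraries, with medians of 3729 against 2462, so neutrophil RNA among B-like cells is not excluded for these 4. The unfolded protein and amino acid stress list had 7 of 23 members higher and 1 lower, or 2 lower without library 3, with herpud1, an endoplasmic reticulum stress gene, at 152 (100.2 to 171) against 25.1 (12.1 to 69.8). T/NK-like cells numbered 68 to 228 per library.

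The negative regulator nr4a1, a nuclear receptor known from the study, differed between libraries by more than counting error. In progenitor-like cells it stood at 3.03, 0.854, 114, 151, 79.3, 215, 189.6 and 49.98 normalised CPM in libraries 1 to 8. The intervals were 0.984 to 7.07 in library 1, 0.0216 to 4.76 in library 2 and 43.9 to 56.6 in library 8. In neutrophil-like cells the values were 0.934, 0.975, 85.1, 134, 56.7, 317, 164 and 54.3, and in macrophage-like cells 5.71, 7.49, 193, 116, 122, 345, 119.997 and 74.6. The summed immediate early genes were also lowest in libraries 1 and 2 in progenitor-like cells, at 1425 and 1270 against at least 3348. In neutrophil-like cells they were 1719 and 1425 against at least 3584. In macrophage-like cells library 4 was lowest, at 3105 against 4028 and 3256 in libraries 1 and 2. Neutrophil-like cells of libraries 1 and 2 lay mostly in 1 cluster (73.5 and 78.8%), while the largest part of those of libraries 3, 4, 6 and 7 lay in another cluster and of those of libraries 5 and 8 in yet another. The ratio of the highest to the lowest library was 84.1, 339 and 60.5 in the 3 classes, with the 1 progenitor-like count of library 2 set to 3. With at least 1000 UMIs and 500 genes per cell the ratio in progenitor-like cells was 10.18. This rests on 539 rather than 2623 cells, and with fewer counts the floor of 3 can lower the ratio. The cells kept by this filter were also clustered and named anew, so which cells were called progenitor-like can differ too. Without library 6 the ratio was 176 in neutrophil-like and 33.8 in macrophage-like cells.

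The cytokine signal inhibitor socs3a was higher in neutrophil-like than in progenitor-like cells in 7 of 8 libraries, with medians of 181 normalised CPM in progenitor-like (12.1 to 703), 642 in neutrophil-like (18.3 to 2256) and 405 in macrophage-like cells (87.3 to 1617). It stood at 12.1, 29.9, 292, 134, 240.05, 703, 164 and 198 in progenitor-like cells of libraries 1 to 8. The ratio of highest to lowest library in neutrophil-like cells was 123, or 42.5 without library 2 and 210.5 with at least 1000 UMIs and 500 genes per cell, and in progenitor-like cells 58.0, or 23.5 without library 1 and 24.1 without library 6. In macrophage-like cells it was 18.5, or 9.21 without library 6. The NF-kB inhibitor nfkbiaa differed less, with 31.4 (12.8 to 63.8) in progenitor-like, 116 (42.4 to 273) in neutrophil-like and 203 (48.8 to 363) in macrophage-like cells.

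The cytokine il1b was nearly absent from progenitor-like cells, with a median of 0.608 normalised CPM from at most 30 counts in a library, and no counts in libraries 2 and 5, which allow up to 2.56 and 1.66. In neutrophil-like cells it stood at 5.23, 0.487, 118, 129, 61.8, 188, 145 and 58.4 in libraries 1 to 8, and in macrophage-like cells the median was 20.4 (1.80 to 36.3). The stress factor atf3 stood at 58.1, 29.7, 260.3, 351, 179, 809, 467 and 214 in neutrophil-like cells, with a median of 101 (4.82 to 330.1) in macrophage-like and 8.55 (0 to 49.6) in progenitor-like cells. The level of atf3 was higher in neutrophil-like than in progenitor-like cells in 8 of 8 libraries, and that of il1b in libraries 1 and 3 to 8. In library 2 il1b had 2 counts in neutrophil-like, 6 in macrophage-like and 0 in progenitor-like cells, and the limit of the latter lies above both values. Among the progenitor-like medians, the filter of 1000 UMIs and 500 genes, with its new clusters, moved asxl1 to 2.84, socs3a to 393, nfkbiaa to 16.7, il1b to 0.946 and atf3 to 13.03. Marker scores moved nr4a1 to 63.1, socs3a to 119.7 and il1b to 1.21.

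**Figure D3:**
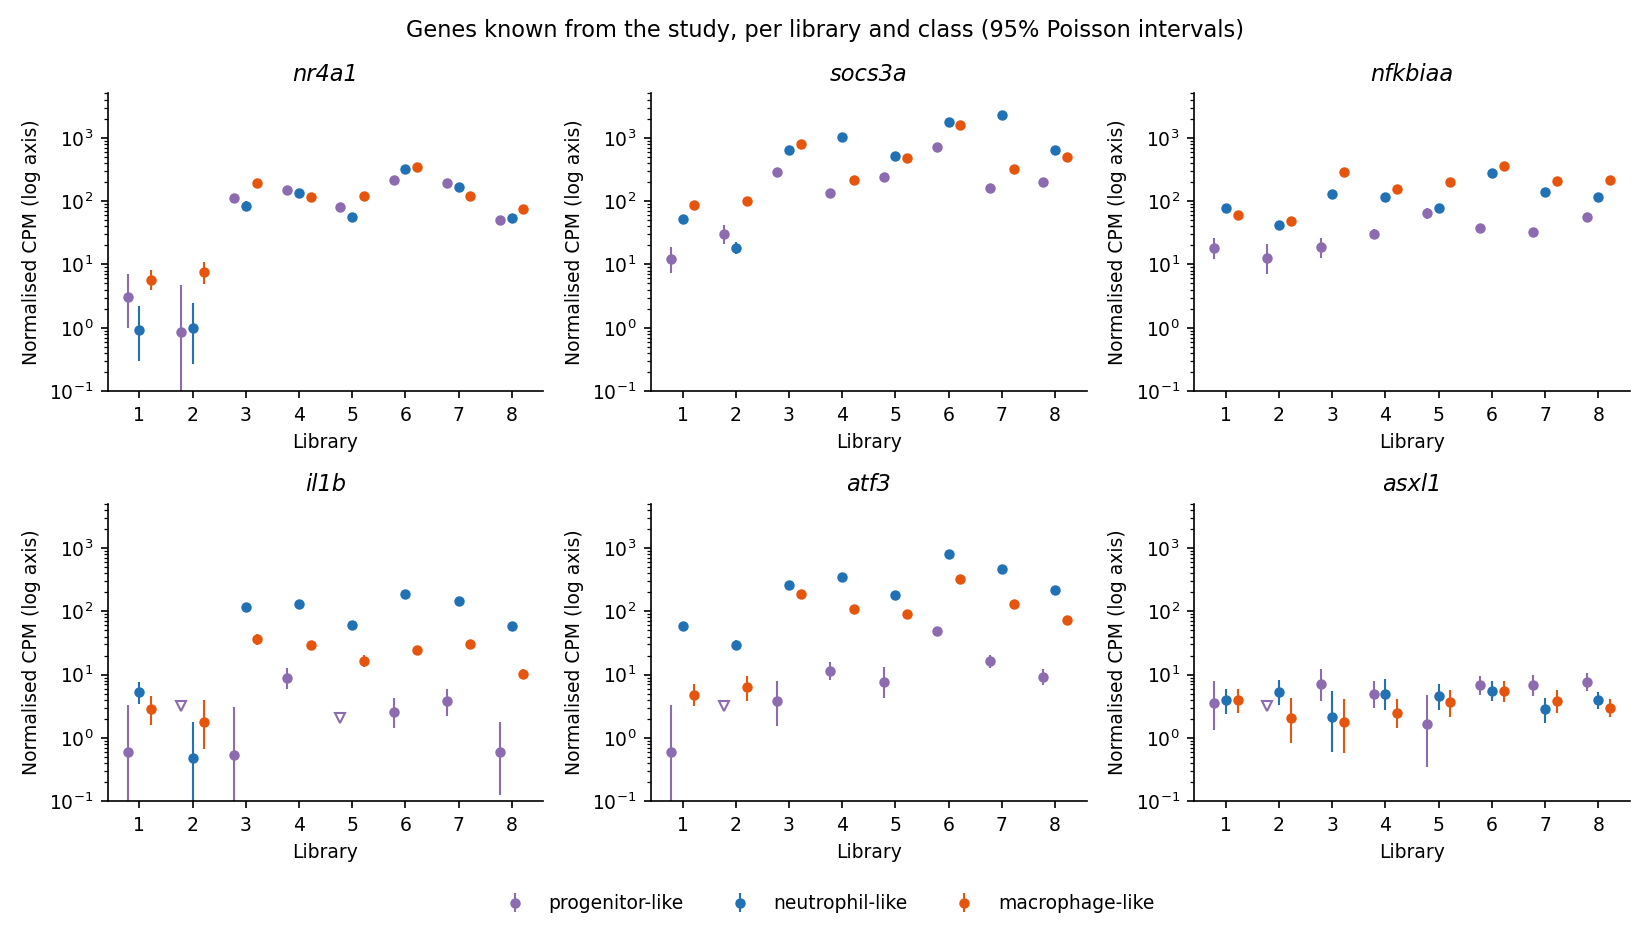
Points give normalised CPM (log axis, with 95% Poisson intervals) of 6 genes in progenitor-like, neutrophil-like and macrophage-like cells of libraries 1 to 8, and open triangles the limit where the count was 0. In neutrophil-like cells nr4a1 lay at 0.934 and 0.975 in libraries 1 and 2 and between 54.3 and 317 in the others.

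Summed over its list, the level of negative regulators in progenitor-like cells was 433, 389, 1865, 1617, 1344, 2959, 1755 and 1235 normalised CPM in libraries 1 to 8. In neutrophil-like cells it was 2301, 1885, 5494, 7571, 3966, 10519, 10157 and 4444. The member cebpb alone ran from 54.7 to 888 in progenitor-like and from 1097 to 4858 in neutrophil-like cells. Immediate early genes, which many stimuli and the handling of cells induce, gave 1425, 1270.0, 3995, 3348, 5609, 7161, 3781 and 6091 in progenitor-like cells. Heat shock genes varied less in these cells, with a median of 3011 (2434 to 3741), and antigen presentation less still, with 3967 (3389 to 4608). Inflammatory effectors had a median of 73.2 (42.7 to 114) in progenitor-like, 1057 (538 to 1642) in neutrophil-like and 567 (223 to 1304) in macrophage-like cells.

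**Figure D4:**
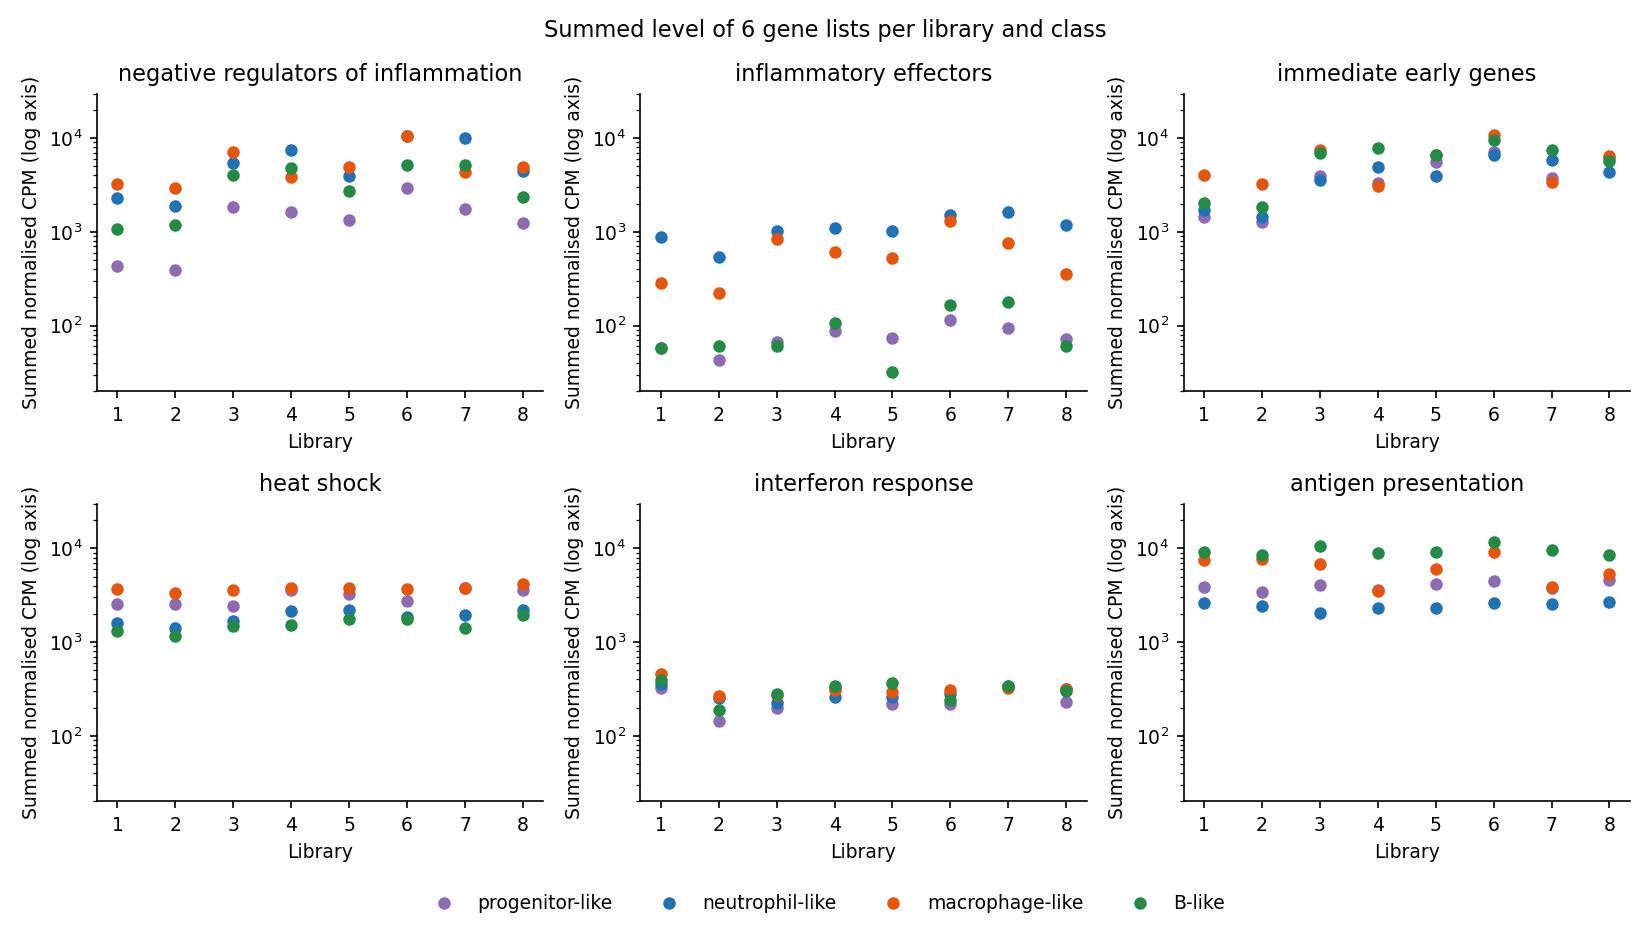
Points give the summed normalised CPM (log axis) of 6 gene lists in progenitor-like, neutrophil-like, macrophage-like and B-like cells of libraries 1 to 8. Negative regulators in progenitor-like cells ran from 389 in library 2 to 2959 in library 6, and antigen presentation from 3389 to 4608.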

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

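The deposited table holds the reporter sequences EGFP and mCherry beside the zebrafish genes, and both had counts in all 8 libraries. EGFP stood at 519.7 CPM in library 1, 789.6 in library 2, 360.1 in library 3, 679.6 in library 4, 1124 in library 5, 403 in library 6, 985 in library 7 and 814 in library 8. mCherry stood at 65.2 in library 1, 74.4 in library 2, 162 in library 3, 17.9 in library 4, 78.2 in library 5, 158 in library 6, 0.832 in library 7 and 0.355 in library 8. The last 2 values rest on 23 and 21 counts, and as no background was measured they do not show that mCherry was expressed there. No counts would have allowed 0.0507 to 0.155 CPM over the 8 libraries. Reporter transcripts were not analysed further here.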

How the results depend on the processing

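No paired analysis was possible because the libraries carry no group and no fish. For the same reason the planned fits between groups were not run, nor their alternatives: edgeR, DESeq2, RLE scaling, an estimated correlation in camera, a replicate block, leaving out libraries by group, removal of spill-over genes, no count filter, list medians and another prior count. Chosen after the data were seen were clusters without the listed genes, the doublet score limit, the low-UMI cluster, CPM without globin or without TMM, and leaving out each library.

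The filter, under which cells were clustered and named anew, moved the median share of all 7 classes. With at least 1000 UMIs and 500 genes the median share of progenitor-like cells was 1.55% (6.17 before), neutrophil-like 33.0 (27.0), macrophage-like 18.65 (10.4), erythroid-like 18.7 (28.1), B-like 4.78 (11.95), T/NK-like 1.58 (3.29) and thrombocyte-like 1.75 (1.21). The ratio of highest to lowest library was 10.18 (84.1) for nr4a1 in progenitor-like and 210.5 (123) for socs3a in neutrophil-like cells. Progenitor-like cells then numbered 539 (2623 before). With doublets kept, neutrophil-like cells made up 29.02%, macrophage-like 11.7 and erythroid-like 30.9, and unnamed cells numbered 2043 (5813 before). By marker score, progenitor-like cells made up 8.004%, erythroid-like 33.1 and thrombocyte-like 2.64.

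In clusters without the listed genes, neutrophil-like cells made up 29.08% and erythroid-like 11.2, where a cluster of 5006 cells with erythroid markers stayed unnamed because liver genes led it. With the low-UMI cluster counted, neutrophil-like cells made up 29.07%. Without erythroid-like cells in the total, progenitor-like cells made up 7.84%, neutrophil-like 36.6, macrophage-like 14.6, B-like 17.96, T/NK-like 4.11 and thrombocyte-like 1.71, which follows from the smaller total.

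Leaving out each library moved the neutrophil-like share between 24.06 and 29.99%. The ratio of highest to lowest library ran from 176 to 339 for nr4a1 in neutrophil-like and from 33.8 to 60.5 in macrophage-like cells, and for socs3a from 23.5 to 58.0 in progenitor-like, 42.5 to 123 in neutrophil-like and 9.21 to 18.5 in macrophage-like cells. Counts of inflammatory effectors and negative regulators higher in neutrophil-like or macrophage-like than in progenitor-like cells stayed within 1.5 times under each of these alternatives.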

Other observations

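All tests in this part were chosen after the values were seen, and no biological explanation was tested, because the libraries carry no group.

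In neutrophil-like cells of libraries 1 to 8 selenou1b, a selenoprotein gene, stood at 112, 129.9, 3.82, 81.5, 62.7, 2.80, 99.8 and 59.97 normalised CPM, and arg2, an arginase gene, at 0.934, 0.731, 124, 151, 15.3, 121, 167 and 13.4. A median of at least 20 CPM with 2 libraries at least 4 times below the third lowest was found for 90 pairs of gene and class. The 2 low libraries were 1 and 2 in 60 pairs of 32 genes, 5 and 8 in 10, 4 and 7 in 8, 3 and 6 in 5, 6 and 7 in 5, 2 and 3 in 1, and 7 and 8 in 1. The 32 genes low in libraries 1 and 2 included nr4a1, socs3a, il1b and atf3, beside junba, jun, fosab, egr2b, egr3 and btg2. The 5 pairs of libraries 6 and 7 are all in thrombocyte-like cells, and 4 are the globin genes hbba1, hbba1.1, hbba2 and hbaa1, which erythroid-like cells carry; these made up 8.22 and 0.760% of the 2 libraries.

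Libraries 1 to 5 held 77, 59, 29, 74 and 50 endothelial-like cells, 6, 6, 28, 14 and 37 kidney-like cells, and 21, 3, 18, 25 and 6 stromal-like cells. Libraries 6, 7 and 8 held 0 of each, which allows up to 0.0646, 0.0585 and 0.0368% of cells. An unnamed cluster led by genes of liver and yolk, among them vtg1 and fabp10a, held 222, 94, 255, 286, 182, 6, 2 and 3 cells in libraries 1 to 8. Of its cells 10.5% had a doublet score of at least 0.25, the highest share of the 30 clusters.

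The nuclear receptor gene nr4a1 was lowest in libraries 1 and 2 in progenitor-like, neutrophil-like and macrophage-like cells. Fewer counts in these libraries are argued against, since the upper bounds of the observed counts reached at most 8.61% of those expected. RNA released by any of the 6 other named classes predicted at most 23.1% of the measured nr4a1, in macrophage-like cells of library 7. Handling before capture stays open, because the summed immediate early genes were also lowest in libraries 1 and 2 in 5 of 7 classes, and the heat shock list in 2 of 7.

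The ribonucleotide reductase gene rrm2, needed for DNA synthesis, stood at 324, 243, 202, 229.96, 0, 286, 191 and 1.43 normalised CPM in erythroid-like cells of libraries 1 to 8, and its copy rrm2.1 at 299.9, 228, 189, 234, 492, 295, 219 and 646. Fewer counts in libraries 5 and 8 are argued against, since the upper bound of the observed counts reached at most 1.42% of those expected. A candidate explanation is that reads of the copies rrm2 and rrm2.1 were counted on 1 of them, since rrm2.1 in library 5, the lower of the 2, was 1.64 times the highest of the other 6 libraries. The sums of both copies in erythroid-like cells were 492 and 647 in libraries 5 and 8 against a median of 467 (391 to 624) in the others. A higher rrm2.1 level in answer to loss of rrm2 would give the same values and stays open. Other classes were divided and were not part of this test. In B-like cells rrm2.1 was also highest in libraries 5 and 8, at 167 and 170 against at most 102. In thrombocyte-like cells it was 61.2 and 113 against up to 196, and in macrophage-like cells 16.3 and 8.39 against up to 55.9. T/NK-like cells had 71.1 and 10.4 against up to 92.3. In progenitor-like and neutrophil-like cells only library 5 lay above all others. In thrombocyte-like cells rrm2 had 0 counts in libraries 5 and 8 and at least 83.7 normalised CPM in the others. In this class alone, both copies together lay lowest in libraries 5 and 8.

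Macrophage-like cells of libraries 4 and 7 lay mostly in cluster 29, which held 224 and 229 of their cells, while cluster 9 held 17 and 5. In cluster 29 the chaperone gene hspa5 stood at 345 CPM against 37.0 in cluster 9, the progranulin gene grn2 at 7387 against 194, and mhc2dab, an MHC class II chain, at 5.32 against 275. Cells of cluster 29 held a median of 20352 UMIs and 2049 genes against 10513 and 1185 in cluster 9, and their median doublet score was 0.073 against 0.046, with 0.440 and 1.27% of cells at a score of at least 0.25. Doublets with neutrophil-, erythroid-, B-, T/NK- or thrombocyte-like cells are argued against, since the lists of these 5 classes reached at most 2.96% of their own level. Doublets with progenitor-like cells are argued against by 9 progenitor markers, which reached a median of 0.450% of their progenitor-like level. However, myb and lmo2 reached 14.7 and 9.17% of that level, and cebpa and hmga1a lay above it. A difference of libraries 4 and 7 shared by all classes stays open: the 6 genes compared, chosen for a gap in macrophage-like cells, had median gaps of 5.66 there, 1.73 in neutrophil-like and 1.33 in progenitor-like cells.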
